A study of Homo sapiens with 24 samples.

How the data were processed

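RNA was sequenced in 24 libraries of the triple-negative lines MDA-MB-231 and MDA-MB-436, with 3 libraries in each of 8 groups. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, total RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra II RNA kit by GENEWIZ, and sequencing ran on an Illumina HiSeq. Per the submitters' processing notes, the authors used cutadapt 2.4, HISAT2, StringTie and edgeR with the GRCh38 build, and the notes do not say what each tool did. Poly(A) selection and the strand of the libraries are not stated. The dose and duration of the PROTAC, whose structure was not used here, and the hairpin sequences are not given in the labels.

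The deposited values are counts, one per Ensembl gene for 60675 genes, per the labels and as tested on the files, where all values were whole numbers. Counts piled up at 4, 8 and 12 among low values, with the number of genes at 4 between 1.2 and 1.64 times that at its neighbours, and the cause was not tested. Intervals from counts alone would be too narrow if several counts stood for 1 fragment, and the floor of 3 counts over a group covers counting error only. Totals ran from 33.4 to 174.7 M counts (M, 1e6 counts), with a median of 64.0 M. Of the identifiers, 57055 were found in GENCODE 29, holding 99.93% of counts, and 56558 in the table of gene names, holding 99.83%.

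Genes were kept by filterByExpr of edgeR 4.0.16 over the 12 libraries of a line, leaving 20675 genes in MDA-MB-231 and 22663 in MDA-MB-436. Library sizes were scaled by TMM, and CPM use these scaled sizes. The 12 libraries of a line were fitted in one quasi-likelihood model with a mean per group and 8 residual degrees of freedom. Each treatment was tested against its own control (MDM2 shRNA against non-targeting shRNA, PROTAC against DMSO), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The PROTAC effect minus the shRNA effect was tested in the same models. Differences between lines were tested in one model of all 24 libraries, with 24719 genes and 16 residual degrees of freedom. The software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, bedtools 2.31.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

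The 30 gene lists covered killer and survival genes of apoptosis, mitosis, DNA replication, ATF4 stress, endoplasmic reticulum chaperones, serine and one-carbon metabolism, hypoxia, interferon, NF-kB, sterol synthesis, NRF2, heat shock, proteasome, ribosome biogenesis, MAPK and AP-1, mesenchymal and epithelial genes, TGF-beta and YAP targets, fatty acid synthesis, autophagy and lysosome, CDK inhibitors and D cyclins, mitochondrial transcripts, replication histones, and markers of leukocytes, endothelium, fibroblasts, luminal breast cells and other cultured lines. Lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01 and adjusted over 120 tests. Counts of list genes are given after adjustment over all genes and over the list alone.

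Genes were named by a rule fixed before the data were examined. It takes MDM2, MDM4, TP63, TP73 and another gene fixed beforehand. It adds, per comparison, the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 1 CPM whose groups do not overlap. Up to 4 members of each list with the smallest adjusted p follow, then the 10 protein-coding genes called in all 4 comparisons whose smallest change is largest. For each test of a difference, the 4 largest positive and 4 largest negative differences complete the rule. Names outside it are marked in the text, and some genes and 1 list are not reported here.

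Recovery was tested on simulated negative binomial counts with the mean levels, dispersions and library sizes of each line. Changes of 1.5-fold were called for 12.5 to 22.9% of genes, 2-fold changes for 31.2 to 59.6%, 4-fold changes for 60.0 to 75.5% and 8-fold changes for 73.5 to 83.3%. Unchanged genes made up 0.855 to 4.9% of calls. A planted list of 30 genes raised by 0.4 on the log2 scale was recovered in each comparison, and a random list was not. Genes were simulated independently, so this does not check the list test where genes are correlated.

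Alternatives set before the data were examined were RLE size factors, no scaling beyond library totals, no filter, a filter of 1 CPM, protein-coding genes only, DESeq2, limma voom, a block for replicate number, robust empirical Bayes, an adjusted p of 0.01, the 6 libraries of a comparison alone, one fit of all 24 libraries, each library left out in turn, and for lists an estimated correlation and fry. Alternatives chosen after seeing the data were counts divided by 4 and rounded, and leaving out genes whose exons overlap another gene. Sequence reads and transcript-level values were not analysed here.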

Results

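RNA sequencing measured transcript levels in MDA-MB-231 and MDA-MB-436, cell lines from triple-negative breast cancers. MDM2 is a ubiquitin ligase, which marks other proteins for degradation. Each line was given a short hairpin RNA (shRNA, which degrades a matching transcript) labelled as directed at MDM2 or a non-targeting shRNA, and in another experiment the MDM2 PROTAC YX-2-30 or its solvent DMSO. A PROTAC (proteolysis-targeting chimera) ties its target protein to a ubiquitin ligase, so that the protein is degraded. The comparisons ask which transcripts change when MDM2 is removed, whether the hairpin and the degrader act alike, and whether the lines respond alike. The 24 libraries formed 8 groups of 3. For MDA-MB-231, total counts in units of 1e6 (M) were 106.9, 69.2 and 65.3 M with the non-targeting shRNA, 61.1, 57.9 and 61.2 M with the MDM2 shRNA label, 75.6, 58.2 and 80.9 M with DMSO and 67.9, 56.7 and 59.5 M with the PROTAC. For MDA-MB-436, the totals in the same order were 64.1, 64.2 and 174.7, then 76.2, 59.4 and 57.2, then 49.6, 59.0 and 64.6, then 63.9, 116.4 and 33.4 M.

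Levels below are mean normalised counts per 1e6 counts (CPM) ± SD over 3 libraries per group, and log2 changes are given ± their standard error. Adjusted p-values of genes come from the edgeR quasi-likelihood test, and those of gene lists from camera, which compares a list with all other genes. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries. The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Coordinates follow GRCh38 with GENCODE 29.

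No fall of MDM2 RNA (ENSG00000135679, chromosome 12, 68808176 to 68850686) was called in the libraries labelled MDM2 shRNA. In MDA-MB-231 it went from 17.7 ± 5.80 to 26 ± 3.77 CPM (log2 change 0.55 ± 0.24, edgeR adjusted p = 0.137), a fold of 1.46 (95% interval 1.01 to 2.12). In MDA-MB-436 it went from 25.4 ± 4.52 to 23.7 ± 7.67 CPM (log2 change -0.11 ± 0.22, edgeR adjusted p = 0.78), a fold of 0.930 (95% interval 0.661 to 1.31), and the sign turned positive without scaling between libraries. A degrader acts on protein, so MDM2 RNA need not change with the PROTAC. It went from 18.5 ± 4.78 to 22.1 ± 2.0 CPM (log2 change 0.26 ± 0.24, edgeR adjusted p = 0.513) in MDA-MB-231. In MDA-MB-436 it went from 36.0 ± 5.54 to 23.5 ± 1.71 CPM (log2 change -0.61 ± 0.23, edgeR adjusted p = 0.0573), a fold of 0.654 (95% interval 0.464 to 0.920), short of the threshold with an unadjusted p of 0.0192 but past it under 5 alternatives, DESeq2 among them. MDM2 shares exons with an unnamed gene (ENSG00000256664), and MDM2 protein was not measured. As no fall of the hairpin's target was called, the groups are named libraries labelled MDM2 shRNA. No change in them is attributed to loss of MDM2 RNA.

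TP73 (ENSG00000078900, chromosome 1, 3652520 to 3736201), a transcription factor, rose in MDA-MB-436 from 4.37 ± 0.138 to 19.96 ± 6.84 CPM (log2 change 2.19 ± 0.27, edgeR adjusted p = 9.61e-05) in the libraries labelled MDM2 shRNA and from 3.64 ± 1.13 to 13 ± 1.57 CPM (log2 change 1.84 ± 0.27, edgeR adjusted p = 0.000309) with the PROTAC. In MDA-MB-231 TP73 rose less in the libraries labelled MDM2 shRNA, from 13.4 ± 0.960 to 17.8 ± 1.12 CPM (log2 change 0.41 ± 0.10, edgeR adjusted p = 0.0153), and did not pass with the PROTAC, from 11.9 ± 0.377 to 13.8 ± 1.83 CPM (log2 change 0.20 ± 0.10, edgeR adjusted p = 0.2). TP73 overlaps a gene on the other strand, and the strand used in counting is not stated.

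MDM4 and TP63 gave little information. MDM4 (ENSG00000198625, chromosome 1, 204516379 to 204558120), a relative and partner of MDM2, passed no threshold, and its SD was as large as its mean in several groups. Its log2 changes in MDA-MB-231 were -0.26 ± 1.08 in the libraries labelled MDM2 shRNA and -1.65 ± 1.10 with the PROTAC, and in MDA-MB-436 they were 1.65 ± 1.01 and 1.43 ± 1.00. TP63 (ENSG00000073282, chromosome 3, 189631416 to 189897279), a relative of TP73, was near 0 everywhere. In MDA-MB-231 it went from 0.256 ± 0.0872 to 0.0167 ± 0.0289 CPM in the libraries labelled MDM2 shRNA (edgeR adjusted p = 0.0493), where its treated libraries held 3 counts together. With the PROTAC all 3 libraries were at 0 (edgeR adjusted p = 0.0163), which is 13-fold lower than DMSO with 0 set to a floor of 3 counts over the group. In MDA-MB-436 TP63 changed by -0.08 ± 1.07 and -0.68 ± 1.07, neither past the threshold.

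CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose in all 4 comparisons. In MDA-MB-436 it went from 6.52 ± 0.155 to 37.3 ± 2.39 CPM (log2 change 2.52 ± 0.16, edgeR adjusted p = 8.67e-07) in the libraries labelled MDM2 shRNA and from 5.87 ± 1.43 to 36.4 ± 4.57 CPM (log2 change 2.63 ± 0.16, edgeR adjusted p = 6.3e-07) with the PROTAC. In MDA-MB-231 it went from 79.3 ± 4.41 to 203 ± 6.0 CPM (log2 change 1.35 ± 0.36, edgeR adjusted p = 0.0185) with the PROTAC. The value for the libraries labelled MDM2 shRNA in that line was picked after it was seen: CDKN1A went from 63.1 ± 27.2 to 158 ± 66.4 CPM (log2 change 1.32 ± 0.36, edgeR adjusted p = 0.0208).

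**Figure D1:**
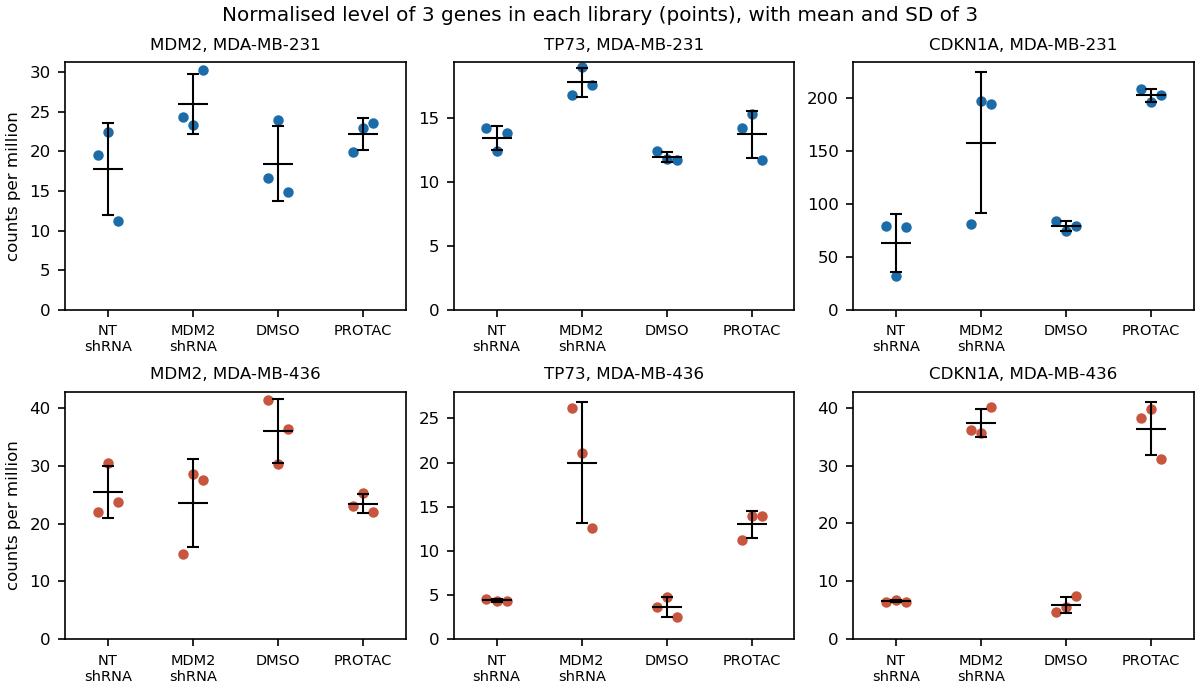
Normalised counts (CPM) of MDM2, TP73 and CDKN1A in each of the 24 libraries, with the mean and SD of each group of 3, for both cell lines. CDKN1A in MDA-MB-436 rises from 5.87 to 36.4 CPM with the PROTAC. MDM2 in the libraries labelled MDM2 shRNA of that line is at 23.7 CPM against 25.4, with no change called.

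In MDA-MB-231, the libraries labelled MDM2 shRNA were set against the non-targeting shRNA to ask what the hairpin changed. DLL4, a Notch ligand, rose from 0.684 ± 0.269 to 4.54 ± 1.00 CPM (log2 change 2.72 ± 0.42, edgeR adjusted p = 0.00085). GPC6, a cell-surface proteoglycan, fell from 10.4 ± 0.424 to 0.480 ± 0.173 CPM (log2 change -4.44 ± 0.36, edgeR adjusted p = 8.87e-06). Of 20675 genes tested, 2292 rose and 2402 fell at an edgeR adjusted p under 0.05, of which 370 and 532 by at least 2-fold. The 3 labelled libraries lay wholly to one side of the 3 controls for 39% of genes, where chance gives 10%. Without scaling between libraries, 68% of the called genes were higher instead of 48.8%, and all genes shifted by 0.10 on the log2 scale.

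The largest rises in the libraries labelled MDM2 shRNA of MDA-MB-231, besides DLL4, were of DUSP26 (3.12 ± 0.50), CA2 (2.77 ± 0.39) and PRSS35 (2.73 ± 0.73), then MAFA (2.54 ± 0.28), HSPB8 (2.35 ± 0.29), CCL26 (2.27 ± 0.44) and MISP (2.21 ± 0.13). DUSP26 is a protein phosphatase, CA2 a carbonic anhydrase, MAFA a transcription factor, HSPB8 a small heat-shock protein and CCL26 a chemokine. Except for MISP (a spindle protein, 1.65 to 7.64 CPM), these genes had under 1 CPM in the controls. By the same rule the largest falls, besides GPC6, were of AKAP6 (-5.84 ± 0.71), GRIK4 (-4.45 ± 0.61) and FRY (-4.32 ± 0.53), then PRKG1 (-4.31 ± 0.39), SLC25A21 (-4.25 ± 0.86), GRIP1 (-4.09 ± 0.34) and NLGN1 (-3.91 ± 0.63). GRIK4 is a glutamate receptor subunit, PRKG1 the kinase activated by cyclic GMP, and NLGN1 a synaptic adhesion protein. FRY shares exons with EEF1DP3, and GPC6, PRKG1, SLC25A21 and GRIP1 overlap a gene on the other strand, so their counts are uncertain.

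The PROTAC was set against DMSO in MDA-MB-231 to ask what the degrader changed. MAFA rose from 0.308 ± 0.0840 to 3.08 ± 0.760 CPM (log2 change 3.30 ± 0.29, edgeR adjusted p = 1.38e-05). TRAPPC9, a vesicle-tethering protein, fell from 26.7 ± 1.5 to 1.81 ± 0.508 CPM (log2 change -3.88 ± 0.19, edgeR adjusted p = 2.19e-07). Of 20675 genes tested, 2290 rose and 2378 fell, 313 and 532 of them by at least 2-fold. The PROTAC and DMSO libraries did not overlap for 39.1% of genes (chance 10%). Without scaling, 65.6% of called genes were higher instead of 49.1%, with a shift of 0.08 on the log2 scale.

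Further large rises with the PROTAC in MDA-MB-231 were of TXNDC5 (2.99 ± 0.79), ZDHHC20 (2.79 ± 0.74) and CA2 (2.57 ± 0.39), then DLL4 (2.55 ± 0.43), TMC8 (2.35 ± 0.38) and ID2 (2.30 ± 0.31). TXNDC5 is a thioredoxin of the endoplasmic reticulum and ID2 an inhibitor of DNA-binding factors. AC009336.2 was listed at 0 in DMSO and reached 2.96 ± 2.34 CPM (3.02 over pooled libraries). With 0 set to a floor of 3 counts over the group, it was 210-fold higher. It shares exons with HOXD3, TXNDC5 shares exons with BLOC1S5-TXNDC5, and ZDHHC20 already stood at 72.3 ± 51.5 CPM with the non-targeting shRNA, so these 3 rises are uncertain. The further large falls were of GRIK4 (-5.11 ± 0.66), AKAP6 (-5.04 ± 0.66), FRY (-4.45 ± 0.53) and SLC25A21 (-4.31 ± 0.87), then GRIK2 (-4.25 ± 0.46), PRKG1 (-4.19 ± 0.38) and GPC6 (-4.11 ± 0.36). Of these 7 falls, 6 were also among the largest in the libraries labelled MDM2 shRNA, and GRIK2 encodes another glutamate receptor subunit.

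Mitotic genes fell in MDA-MB-231. Of 32 measured, 24 fell, 1 rose and 7 did not pass (25 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.45 and camera adjusted p = 1.69e-16 in the libraries labelled MDM2 shRNA. With the PROTAC, 20 fell, 0 rose and 12 did not pass (23 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.38 and camera adjusted p = 4.02e-14. CDC20, which activates the anaphase-promoting complex, changed by -1.22 ± 0.036 and -1.23 ± 0.036, and the mitotic kinase gene PLK1 by -1.49 ± 0.078 and -1.32 ± 0.078. S-phase and replication genes rose as a list: of 32, 16 rose, 5 fell and 11 did not pass (21 rose and 5 fell adjusted over the list alone), with a median log2 change of 0.20 and camera adjusted p = 0.000149 in the libraries labelled MDM2 shRNA. The PROTAC gave a similar list result: 17 rose, 3 fell and 12 did not pass (20 rose and 4 fell adjusted over the list alone), with a median log2 change of 0.20 and camera adjusted p = 1.43e-05. RRM2, a subunit of ribonucleotide reductase, rose by 1.17 ± 0.038 and 1.19 ± 0.038, while the helicase subunit gene MCM5 changed by -0.79 ± 0.056 and -0.85 ± 0.056. The replication result was lost without genes whose exons overlap another gene (camera adjusted p = 0.12 and 0.0687).

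Killer genes of the BCL-2 family and caspases rose as a list in MDA-MB-231, although many of them did not pass on their own. Of 18, 7 rose, 1 fell and 10 did not pass (7 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.23 and camera adjusted p = 0.00399 in the libraries labelled MDM2 shRNA. Under the degrader, 8 rose, 1 fell and 9 did not pass (8 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.34 and camera adjusted p = 0.000789. Outside this list, PIDD1, a death-domain protein, rose by 1.048 ± 0.070 and 0.73 ± 0.070, and the DNA polymerase gene POLH by 0.45 ± 0.047 and 0.51 ± 0.047.

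Interferon-response genes rose in MDA-MB-231. Of 30 measured, 20 rose, 1 fell and 9 did not pass (22 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.69 and camera adjusted p = 3.39e-14 in the libraries labelled MDM2 shRNA. With the PROTAC, 20 rose, 0 fell and 10 did not pass (20 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.60 and camera adjusted p = 2.06e-12. IFIT2 rose by 1.23 ± 0.082 and 1.43 ± 0.082, and ISG15, a ubiquitin-like protein, by 0.91 ± 0.068 and 0.83 ± 0.068. Among 23 NF-kB targets and cytokines, 7 rose, 1 fell and 15 did not pass (12 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.35 and camera adjusted p = 2.9e-05 in the libraries labelled MDM2 shRNA. The PROTAC counts were 8 rose, 1 fell and 14 did not pass (9 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.52 and camera adjusted p = 0.000144. ICAM1, an adhesion molecule, rose by 1.09 ± 0.084 and 1.12 ± 0.084, whereas the cytokine gene LIF changed by -0.56 ± 0.053 and -0.57 ± 0.053.

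Endoplasmic reticulum chaperone, fatty acid synthesis and ribosome biogenesis genes fell as lists in MDA-MB-231. Of 18 endoplasmic reticulum chaperone genes, 9 fell and 9 did not pass (10 fell adjusted over the list alone), with a median log2 change of -0.30 and camera adjusted p = 1.27e-05 in the libraries labelled MDM2 shRNA. With the PROTAC, 9 fell, 0 rose and 9 did not pass (9 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.27 and camera adjusted p = 0.000338. HSPA5 (BiP) fell by 0.80 and 0.71 on the log2 scale. Among 14 fatty acid synthesis genes, 8 fell and 6 did not pass (8 fell adjusted over the list alone), with a median log2 change of -0.29 and camera adjusted p = 2.91e-05 in the libraries labelled MDM2 shRNA. Under the PROTAC, 7 fell and 7 did not pass (7 fell adjusted over the list alone), with a median log2 change of -0.15 and camera adjusted p = 0.0012 (adjusted p = 0.0767 with an estimated correlation). SCD, a desaturase, changed by -0.70 ± 0.028 and -0.61 ± 0.027. Of 25 ribosome biogenesis genes, 12 fell, 0 rose and 13 did not pass (12 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.20 and camera adjusted p = 0.0025 in the libraries labelled MDM2 shRNA. For the degrader, 9 fell, 2 rose and 14 did not pass (10 fell and 3 rose adjusted over the list alone), with a median log2 change of -0.14 and camera adjusted p = 0.0231 (adjusted p = 0.0994 with an estimated correlation). RRS1, needed for ribosome assembly, changed by -0.51 ± 0.054 and -0.42 ± 0.054.

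Mesenchymal and TGF-beta or YAP target genes moved both ways in MDA-MB-231. Of 22 mesenchymal genes, 10 fell, 5 rose and 7 did not pass (10 fell and 6 rose adjusted over the list alone), with a median log2 change of -0.16 and camera adjusted p = 0.0231 (adjusted p = 0.144 with an estimated correlation) in the libraries labelled MDM2 shRNA. With the PROTAC, 9 fell, 6 rose and 7 did not pass (10 fell and 6 rose adjusted over the list alone), with a median log2 change of -0.21 and camera adjusted p = 0.0292 (adjusted p = 0.162 with an estimated correlation). AXL, a receptor kinase, changed by -0.72 ± 0.025 and -0.71 ± 0.025, and the collagenase gene MMP1 by 0.97 ± 0.046 and 0.99 ± 0.046. Among 18 TGF-beta and YAP targets, 7 fell, 4 rose and 7 did not pass (9 fell and 5 rose adjusted over the list alone), with a median log2 change of -0.23 and camera adjusted p = 0.000144 (adjusted p = 0.126 with an estimated correlation) in the libraries labelled MDM2 shRNA. For the PROTAC, 7 fell, 4 rose and 7 did not pass (7 fell and 4 rose adjusted over the list alone), with a median log2 change of -0.12 and camera adjusted p = 0.00399 (adjusted p = 0.228 with an estimated correlation). LTBP1, which binds latent TGF-beta, changed by -2.29 ± 0.086 and -1.96 ± 0.084. Without genes whose exons overlap another gene, the mesenchymal result was lost (camera adjusted p = 0.0964 and 0.187), as were the TGF-beta and YAP result (camera adjusted p = 0.187 and 0.732) and the ribosome biogenesis result (camera adjusted p = 0.0665 and 0.297).

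Replication-dependent histone transcripts, mostly without poly(A) tails, fell in MDA-MB-231, so RNA selection may differ between groups. Of 13 measured, 10 fell and 3 did not pass (13 fell adjusted over the list alone), with a median log2 change of -1.39 and camera adjusted p = 2.06e-12 in the libraries labelled MDM2 shRNA. With the PROTAC, 11 fell and 2 did not pass (11 fell adjusted over the list alone), with a median log2 change of -1.17 and camera adjusted p = 8.67e-12. H2AC6 changed by -2.42 ± 0.075 and -2.26 ± 0.074, and H1-2 by -1.52 ± 0.060 in both. Of 13 genes of the mitochondrial genome, 5 fell and 8 did not pass (6 fell adjusted over the list alone), with a median log2 change of -0.18 and camera adjusted p = 0.0197 (adjusted p = 0.335 with an estimated correlation) in the libraries labelled MDM2 shRNA. Under the PROTAC, 5 fell and 8 did not pass (8 fell adjusted over the list alone), with a median log2 change of -0.18 and camera adjusted p = 0.0131 (adjusted p = 0.309 with an estimated correlation). Mitochondrial transcripts took 5.64% ± 0.089 (non-targeting shRNA), 5.48% ± 0.1 (MDM2 shRNA label), 5.75% ± 0.28 (DMSO) and 5.59% ± 0.06 (PROTAC) of counts. MT-ND4 changed by -0.28 ± 0.067 and -0.40 ± 0.067.

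Among the other lists in MDA-MB-231, stress genes under ATF4 passed with the PROTAC: of 24, 9 fell, 2 rose and 13 did not pass (9 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.10 and camera adjusted p = 0.0395 (adjusted p = 0.157 with an estimated correlation). In the libraries labelled MDM2 shRNA, 8 fell, 3 rose and 13 did not pass (9 fell and 5 rose adjusted over the list alone), with a median log2 change of -0.09 and camera adjusted p = 0.0671. DDIT4, an inhibitor of mTORC1, changed by -0.99 ± 0.055 and -1.01 ± 0.055. The lists that passed with neither treatment contained changed genes of both directions, such as CCND1 (cyclin D1, -0.80 ± 0.039 in the libraries labelled MDM2 shRNA and -0.86 ± 0.039 with the PROTAC), ADM (adrenomedullin, 1.74 ± 0.10 and 1.73 ± 0.10), DUSP1 (a MAP kinase phosphatase, 1.64 ± 0.064 and 1.72 ± 0.065), MTHFD1L (a folate enzyme, -0.95 ± 0.051 and -0.76 ± 0.050) and HMOX1 (heme oxygenase 1, 0.68 ± 0.094 and 0.87 ± 0.094).

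The lists that passed in neither comparison of MDA-MB-231 are given by their genes past the edgeR threshold, first over all genes tested. The 9 survival genes of the BCL-2 and IAP families had 1 higher and 4 lower (1 and 4 over the list alone, camera adjusted p = 0.0674) in the libraries labelled MDM2 shRNA and 1 higher and 4 lower (1 and 4 over the list alone, camera adjusted p = 0.235) with the PROTAC. The 11 serine and one-carbon genes had 1 higher and 3 lower (1 and 3 over the list alone, camera adjusted p = 0.191) in the libraries labelled MDM2 shRNA and 2 higher and 3 lower (2 and 3 over the list alone, camera adjusted p = 0.36) with the PROTAC. The 24 hypoxia targets had 2 higher and 7 lower (3 and 7 over the list alone, camera adjusted p = 0.149) in the libraries labelled MDM2 shRNA and 1 higher and 7 lower (1 and 7 over the list alone, camera adjusted p = 0.149) with the PROTAC. The 25 sterol synthesis genes had 3 higher and 7 lower (5 and 7 over the list alone, camera adjusted p = 0.736) in the libraries labelled MDM2 shRNA and 3 higher and 6 lower (5 and 6 over the list alone, camera adjusted p = 0.962) with the PROTAC. The 21 NRF2 targets had 4 higher and 4 lower (4 and 5 over the list alone, camera adjusted p = 0.622) in the libraries labelled MDM2 shRNA and 3 higher and 4 lower (6 and 4 over the list alone, camera adjusted p = 0.365) with the PROTAC. The 19 heat-shock genes had 3 higher and 4 lower (4 and 4 over the list alone, camera adjusted p = 0.773) in the libraries labelled MDM2 shRNA and 3 higher and 3 lower (4 and 4 over the list alone, camera adjusted p = 0.728) with the PROTAC. The 31 proteasome subunits had 9 higher and 2 lower (9 and 3 over the list alone, camera adjusted p = 0.0668) in the libraries labelled MDM2 shRNA and 5 higher and 2 lower (5 and 2 over the list alone, camera adjusted p = 0.182) with the PROTAC. The 22 MAPK and AP-1 genes had 6 higher and 7 lower (6 and 8 over the list alone, camera adjusted p = 0.197) in the libraries labelled MDM2 shRNA and 5 higher and 6 lower (5 and 6 over the list alone, camera adjusted p = 0.261) with the PROTAC. 

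Cell-identity lists and the remaining pathways of MDA-MB-231 passed in neither comparison. The 16 epithelial genes had 1 higher and 3 lower (2 and 3 over the list alone, camera adjusted p = 0.619) in the libraries labelled MDM2 shRNA and 1 higher and 4 lower (1 and 4 over the list alone, camera adjusted p = 0.728) with the PROTAC. The 23 autophagy and lysosome genes had 5 higher and 3 lower (6 and 4 over the list alone, camera adjusted p = 0.453) in the libraries labelled MDM2 shRNA and 6 higher and 4 lower (7 and 4 over the list alone, camera adjusted p = 0.193) with the PROTAC. The 10 CDK inhibitors and D cyclins had 2 higher and 5 lower (3 and 5 over the list alone, camera adjusted p = 0.106) in the libraries labelled MDM2 shRNA and 1 higher and 2 lower (1 and 2 over the list alone, camera adjusted p = 0.255) with the PROTAC. The 5 leukocyte markers had 0 higher and 2 lower (0 and 2 over the list alone, camera adjusted p = 0.548) in the libraries labelled MDM2 shRNA and 0 higher and 2 lower (0 and 2 over the list alone, camera adjusted p = 0.736) with the PROTAC. The 5 endothelial markers had 1 higher and 1 lower (1 and 1 over the list alone, camera adjusted p = 0.892) in the libraries labelled MDM2 shRNA and 0 higher and 1 lower (0 and 1 over the list alone, camera adjusted p = 0.88) with the PROTAC. The 6 fibroblast markers had 2 higher and 1 lower (3 and 1 over the list alone, camera adjusted p = 0.446) in the libraries labelled MDM2 shRNA and 2 higher and 1 lower (2 and 1 over the list alone, camera adjusted p = 0.477) with the PROTAC. The 11 luminal breast markers had 1 higher and 2 lower (1 and 2 over the list alone, camera adjusted p = 0.211) in the libraries labelled MDM2 shRNA and 1 higher and 3 lower (1 and 3 over the list alone, camera adjusted p = 0.317) with the PROTAC. The 5 liver, kidney and neural markers had 1 higher and 1 lower (1 and 1 over the list alone, camera adjusted p = 0.894) in the libraries labelled MDM2 shRNA and 0 past the threshold with the PROTAC by edgeR (0 over the list alone, camera adjusted p = 0.91), where 1 had an unadjusted p under 0.05, DESeq2 called 1 and voom 0. For the sterol, heat-shock, MAPK, epithelial, CDK inhibitor, endothelial and last of these lists in the libraries labelled MDM2 shRNA, the median, the mean and the test did not share one sign. With the PROTAC this held for the survival, sterol, MAPK, epithelial, CDK inhibitor and leukocyte lists. Without scaling between libraries, the proteasome list passed as higher in MDA-MB-231 (camera adjusted p = 0.00244 and 0.0205).

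Genes with a long genomic span fell more often than others in MDA-MB-231, a grouping chosen after the values were seen. Of 256 protein-coding genes spanning over 400 kb, 68.8% fell in the libraries labelled MDM2 shRNA and 66.4% with the PROTAC, with median log2 changes of -0.95 and -0.89. Among 664 genes of 200 to 400 kb, 46.7% and 42.9% fell. Among 4348 genes under 20 kb, 11.7% and 12.5% fell. In MDA-MB-436, 28.3% and 39.4% of 279 genes over 400 kb fell, with median log2 changes of -0.12 and -0.28. The list of largest falls in MDA-MB-231 includes such genes as AKAP6, GPC6, PRKG1 and NLGN1.

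**Figure D2:**
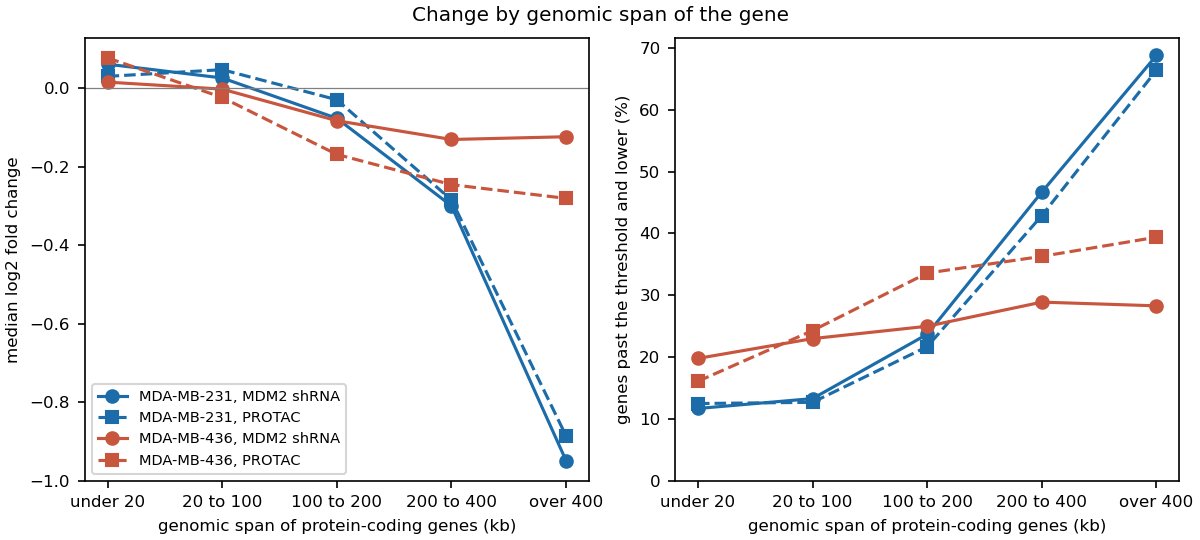
Median log2 change of protein-coding genes and percent of genes lower (edgeR adjusted p under 0.05), by genomic span in kb, for the 4 comparisons. In MDA-MB-231 the percent lower rises from 11.7 under 20 kb to 68.8 over 400 kb in the libraries labelled MDM2 shRNA and from 12.5 to 66.4 with the PROTAC.

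The same question was asked of the libraries labelled MDM2 shRNA in MDA-MB-436. CCL4, a chemokine, rose from 0.267 ± 0.0745 to 11.9 ± 1.86 CPM (log2 change 5.52 ± 0.33, edgeR adjusted p = 4.74e-07). SEMA3D, a secreted guidance protein, fell from 11.2 ± 0.765 to 2.24 ± 0.651 CPM (log2 change -2.32 ± 0.19, edgeR adjusted p = 5.2e-06). Of 22663 genes tested, 3622 rose and 3274 fell at an edgeR adjusted p under 0.05, of which 1500 and 510 by at least 2-fold. The groups did not overlap for 52.0% of genes (chance 10%). Without scaling between libraries, 72.8% of called genes were higher instead of 52.5%, and all genes shifted by 0.18 on the log2 scale.

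Further large rises in the libraries labelled MDM2 shRNA of MDA-MB-436 were of MYH2 (6.44 ± 0.73), NF2 (5.86 ± 0.54) and WDFY4 (5.17 ± 1.12), then AKR1B15 (4.84 ± 0.40), ARHGAP40 (4.62 ± 0.74) and ANO9 (4.61 ± 0.38). MYH2 is a muscle myosin, and NF2 encodes the tumour suppressor merlin. NF2 went from 0.196 ± 0.0281 to 11.7 ± 1.78 CPM in this line. TRIM39-RPP21, a read-through gene that shares exons with TRIM39, was listed at 0 in the controls and reached 2.76 ± 1.15 CPM (2.88 over pooled libraries). With 0 set to a floor of 3 counts over the group, it was 271-fold higher. Further large falls were of TOMM6 (-3.73 ± 0.54), SPIN1 (-3.12 ± 0.61) and FGFBP1 (-2.56 ± 0.77), then IGFBP5 (-2.52 ± 0.32), COL8A1 (-2.31 ± 0.31) and GPRASP2 (-2.20 ± 0.68). TOMM6 is a subunit of the mitochondrial import pore, IGFBP5 binds insulin-like growth factors, and COL8A1 is a collagen. TOMM6 and GPRASP2 share exons with other genes, and SPIN1 varied widely in the controls (148 ± 85.7 CPM), so these falls are uncertain.

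With the PROTAC in MDA-MB-436, MMP3, a matrix metalloproteinase, fell from 3.34 ± 0.230 to 0.414 ± 0.224 CPM (log2 change -2.95 ± 0.33, edgeR adjusted p = 4.08e-05). CCL4 rose from 0.183 ± 0.0921 to 11.8 ± 2.56 CPM (log2 change 5.97 ± 0.35, edgeR adjusted p = 3.92e-07). Of 22663 genes tested, 3916 rose and 3418 fell, 1689 and 635 of them by at least 2-fold. The PROTAC and DMSO libraries of this line did not overlap for 42.3% of genes (chance 10%). Without scaling, 70.9% of called genes were higher instead of 53.4%, with a shift of 0.17 on the log2 scale.

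Among the largest rises with the PROTAC in MDA-MB-436, 4 genes were listed at 0 with DMSO. With 0 set to a floor of 3 counts over the group, the kinase gene CAMK1G was 181-fold higher (3.33 ± 0.325 CPM), WDFY4 172-fold, and the potassium channel gene KCNB2 and MYH2 156-fold each. The others were NF2 (6.38 ± 0.58), ARHGAP40 (5.32 ± 0.82) and EGFL6 (5.32 ± 0.59). The further large falls were of PCDHGA4 (-2.99 ± 1.04), IGFBP5 (-2.88 ± 0.33), GPRASP2 (-2.83 ± 0.68) and ZBED6 (-2.76 ± 0.82), then SSTR1 (-2.44 ± 0.51), PCDHGA1 (-2.41 ± 0.85) and MAP2K6 (-2.38 ± 0.67). SSTR1 is a somatostatin receptor, and MAP2K6 activates the p38 kinases. PCDHGA4, PCDHGA1, GPRASP2 and ZBED6 share exons with other genes, and the protocadherins varied in DMSO (2.82 ± 2.87 CPM for PCDHGA4).

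Mitotic genes fell and replication genes rose in MDA-MB-436. Of 32 mitotic genes, 23 fell, 1 rose and 8 did not pass (25 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.51 and camera adjusted p = 1.71e-14 in the libraries labelled MDM2 shRNA. With the PROTAC, 25 fell, 1 rose and 6 did not pass (25 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.58 and camera adjusted p = 3.39e-14. KIF20A, a kinesin of cytokinesis, changed by -1.71 ± 0.076 and -1.82 ± 0.077, and CCNB1 (cyclin B1) by -1.56 ± 0.076 and -1.57 ± 0.076. Of 32 replication genes, 28 rose and 4 did not pass (28 rose adjusted over the list alone), with a median log2 change of 0.62 and camera adjusted p = 2.74e-21 in the libraries labelled MDM2 shRNA. Under the PROTAC, 27 rose and 5 did not pass (29 rose adjusted over the list alone), with a median log2 change of 0.63 and camera adjusted p = 3.94e-20. The cell-cycle activator gene E2F2 rose by 2.48 ± 0.082 and 2.42 ± 0.082, and CDC6, which loads the replicative helicase, by 1.28 ± 0.054 and 1.18 ± 0.053.

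Killer genes of apoptosis passed as a list in MDA-MB-436, although most of them did not pass on their own. Of 19 killer genes of the BCL-2 family and caspases, 6 rose and 13 did not pass (6 rose adjusted over the list alone), with a median log2 change of 0.17 and camera adjusted p = 0.0141 (adjusted p = 0.194 with an estimated correlation) in the libraries labelled MDM2 shRNA. Under the degrader, 6 rose and 13 did not pass (7 rose adjusted over the list alone), with a median log2 change of 0.13 and camera adjusted p = 0.0141 (adjusted p = 0.194 with an estimated correlation). HRK, a BH3-only protein, rose by 1.69 ± 0.12 and 1.52 ± 0.12, and BBC3 (PUMA) by 1.37 ± 0.19 in the libraries labelled MDM2 shRNA. This list did not pass without genes whose exons overlap another gene (camera adjusted p = 0.117 and 0.167). Outside it, GADD45A, induced by DNA damage, rose by 2.93 ± 0.065 and 3.09 ± 0.065, and the nuclease gene AEN by 1.34 ± 0.11 and 1.21 ± 0.11.

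Inflammatory and stress genes rose in MDA-MB-436. Of 24 NF-kB targets and cytokines, 14 rose, 3 fell and 7 did not pass (15 rose and 5 fell adjusted over the list alone), with a median log2 change of 0.96 and camera adjusted p = 3.71e-15 in the libraries labelled MDM2 shRNA. With the PROTAC, 15 rose, 3 fell and 6 did not pass (16 rose and 4 fell adjusted over the list alone), with a median log2 change of 1.13 and camera adjusted p = 5.88e-18. TNFAIP3 (A20) rose from 117 ± 1.01 to 678 ± 17.3 CPM and from 126 ± 1.66 to 699 ± 65.0 CPM, and the chemokine gene CXCL8 by 2.75 ± 0.082 and 3.0 ± 0.083. Of 24 ATF4 stress genes, 12 rose, 2 fell and 10 did not pass (14 rose and 4 fell adjusted over the list alone), with a median log2 change of 0.56 and camera adjusted p = 5.46e-05 (adjusted p = 0.151 with an estimated correlation) in the libraries labelled MDM2 shRNA. Under the PROTAC, 11 rose, 3 fell and 10 did not pass (12 rose and 3 fell adjusted over the list alone), with a median log2 change of 0.50 and camera adjusted p = 5.53e-05 (adjusted p = 0.145 with an estimated correlation). DDIT3 (CHOP) rose by 1.96 ± 0.10 and 2.0 ± 0.10. Of 22 MAPK and AP-1 genes, 11 rose, 2 fell and 9 did not pass (12 rose and 4 fell adjusted over the list alone), with a median log2 change of 0.43 and camera adjusted p = 0.000252 (adjusted p = 0.0767 with an estimated correlation) in the libraries labelled MDM2 shRNA. For the degrader, 11 rose, 3 fell and 8 did not pass (11 rose and 4 fell adjusted over the list alone), with a median log2 change of 0.38 and camera adjusted p = 7.72e-05 (adjusted p = 0.0685 with an estimated correlation). EGR1 rose by 3.53 ± 0.10 and 3.5 ± 0.10.

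Chaperone genes fell in MDA-MB-436. Of 19 heat-shock genes, 17 fell, 1 rose and 1 did not pass (18 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.92 and camera adjusted p = 8.77e-29 in the libraries labelled MDM2 shRNA. With the PROTAC, 17 fell, 1 rose and 1 did not pass (17 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.89 and camera adjusted p = 1.3e-24. HSPD1, the mitochondrial chaperonin, changed by -1.22 ± 0.044 and -1.23 ± 0.044, and HSPA1A (HSP70) by -1.62 ± 0.065 and -1.60 ± 0.065. Of 18 endoplasmic reticulum chaperone genes, 11 fell, 3 rose and 4 did not pass (11 fell and 3 rose adjusted over the list alone), with a median log2 change of -0.56 and camera adjusted p = 2.14e-06 in the libraries labelled MDM2 shRNA. Under the PROTAC, 10 fell, 2 rose and 6 did not pass (11 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.45 and camera adjusted p = 1.04e-05. PDIA4 changed by -1.10 ± 0.057 and -1.06 ± 0.057. Of 31 proteasome subunits, 16 fell, 2 rose and 13 did not pass (17 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.32 and camera adjusted p = 0.000374 (adjusted p = 0.0742 with an estimated correlation) in the libraries labelled MDM2 shRNA. For the PROTAC, 11 fell, 3 rose and 17 did not pass (11 fell and 3 rose adjusted over the list alone), with a median log2 change of -0.14 and camera adjusted p = 0.0339 (adjusted p = 0.237 with an estimated correlation), a median smaller than the shift of all genes without scaling, where the list did not pass. PSMD1 changed by -0.71 ± 0.063 and -0.77 ± 0.063.

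Lipid and redox genes fell in MDA-MB-436. Of 15 fatty acid synthesis genes, 11 fell and 4 did not pass (13 fell adjusted over the list alone), with a median log2 change of -0.76 and camera adjusted p = 1.66e-13 in the libraries labelled MDM2 shRNA. With the PROTAC, 11 fell, 0 rose and 4 did not pass (12 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.76 and camera adjusted p = 5.52e-14. SCD changed by -1.45 ± 0.055 and -1.61 ± 0.055, and FASN by -1.33 ± 0.065 and -1.33 ± 0.065. Of 25 sterol synthesis genes, 13 fell, 2 rose and 10 did not pass (14 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.47 and camera adjusted p = 6.23e-07 in the libraries labelled MDM2 shRNA. Under the PROTAC, 13 fell, 2 rose and 10 did not pass (14 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.37 and camera adjusted p = 1.69e-06. Of 21 NRF2 targets, 11 fell, 1 rose and 9 did not pass (12 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.52 and camera adjusted p = 2.51e-05 in the libraries labelled MDM2 shRNA. For the degrader, 11 fell, 2 rose and 8 did not pass (12 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.50 and camera adjusted p = 3.58e-05. TKT, a pentose phosphate enzyme, changed by -1.06 ± 0.067 and -0.92 ± 0.066.

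Mesenchymal genes and TGF-beta or YAP targets fell as lists in MDA-MB-436. Of 24 mesenchymal genes, 12 fell, 3 rose and 9 did not pass (12 fell and 4 rose adjusted over the list alone), with a median log2 change of -0.33 and camera adjusted p = 7.26e-06 in the libraries labelled MDM2 shRNA. With the PROTAC, 13 fell, 2 rose and 9 did not pass (13 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.45 and camera adjusted p = 9.54e-07. LOXL2 changed by -1.44 ± 0.074 and -1.47 ± 0.074. Of 18 TGF-beta and YAP targets, 10 fell, 1 rose and 7 did not pass (10 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.42 and camera adjusted p = 8.86e-05 in the libraries labelled MDM2 shRNA. Under the PROTAC, 10 fell, 1 rose and 7 did not pass (10 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.43 and camera adjusted p = 2.02e-05. ANKRD1, a YAP target, rose instead, by 3.32 ± 0.20 and 2.35 ± 0.20. Of 24 hypoxia targets, 12 fell, 3 rose and 9 did not pass (12 fell and 3 rose adjusted over the list alone), with a median log2 change of -0.39 and camera adjusted p = 0.0097 (adjusted p = 0.0689 with an estimated correlation) in the libraries labelled MDM2 shRNA. For the degrader, 11 fell, 2 rose and 11 did not pass (11 fell and 3 rose adjusted over the list alone), with a median log2 change of -0.15 and camera adjusted p = 0.00409, a median smaller than the shift without scaling. The hypoxia result was lost without genes whose exons overlap another gene (camera adjusted p = 0.228 and 0.125), and the glycolytic gene PGK1 changed by -1.11 ± 0.054 and -1.11 ± 0.054.

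Genes of the mitochondrial genome, a preset sign of RNA quality, fell in MDA-MB-436 too, so a difference in RNA quality is not ruled out in either line. Of 13, 12 fell and 1 did not pass (12 fell adjusted over the list alone), with a median log2 change of -0.63 and camera adjusted p = 2.32e-11 in the libraries labelled MDM2 shRNA. With the PROTAC, 12 fell and 1 did not pass (13 fell adjusted over the list alone), with a median log2 change of -0.49 and camera adjusted p = 1.49e-07. MT-ND6 changed by -0.84 ± 0.051 and -0.61 ± 0.050. Their share of counts was 7.13% ± 0.13 (non-targeting shRNA), 5.49% ± 0.015 (MDM2 shRNA label), 6.85% ± 0.099 (DMSO) and 5.49% ± 0.01 (PROTAC). Of 19 replication-dependent histone genes, edgeR called 0 in the libraries labelled MDM2 shRNA, over all genes or over the list alone (median log2 change 0.11, camera adjusted p = 0.973), with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by voom. With the PROTAC edgeR also called 0 of them (median log2 change -0.01, camera adjusted p = 0.962), with 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. H2BC5 changed by 0.45 ± 0.24 and 0.61 ± 0.24.

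Interferon-response genes passed narrowly in MDA-MB-436 in the libraries labelled MDM2 shRNA: of 35, 12 rose, 2 fell and 21 did not pass (13 rose and 2 fell adjusted over the list alone), with a median log2 change of 0.23 and camera adjusted p = 0.0486 (adjusted p = 0.083 with an estimated correlation). With the PROTAC, 10 rose, 3 fell and 22 did not pass (12 rose and 3 fell adjusted over the list alone), with a median log2 change of 0.10 and camera adjusted p = 0.106. IRF7, which drives interferon genes, rose by 1.97 ± 0.12 and 2.12 ± 0.12, whereas IFIT1 changed by -0.88 ± 0.084 and -0.87 ± 0.084. Lists that passed with neither treatment held changed genes too, such as CCND1 (-0.87 ± 0.054 and -0.95 ± 0.054), BCL2 (1.17 ± 0.12 and 0.67 ± 0.12) and the integrin gene ITGAM (3.33 ± 0.17 and 3.21 ± 0.17).

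The lists that passed in neither comparison of MDA-MB-436 are given in the same way as for MDA-MB-231. The 9 survival genes of the BCL-2 and IAP families had 3 higher and 3 lower (3 and 3 over the list alone, camera adjusted p = 0.613) in the libraries labelled MDM2 shRNA and 2 higher and 3 lower (2 and 3 over the list alone, camera adjusted p = 0.821) with the PROTAC. The 11 serine and one-carbon genes had 3 higher and 2 lower (4 and 2 over the list alone, camera adjusted p = 0.925) in the libraries labelled MDM2 shRNA and 2 higher and 3 lower (3 and 3 over the list alone, camera adjusted p = 0.987) with the PROTAC. The 25 ribosome biogenesis genes had 2 higher and 7 lower (2 and 8 over the list alone, camera adjusted p = 0.1) in the libraries labelled MDM2 shRNA and 4 higher and 7 lower (4 and 7 over the list alone, camera adjusted p = 0.193) with the PROTAC. The 23 autophagy and lysosome genes had 5 higher and 5 lower (9 and 6 over the list alone, camera adjusted p = 0.624) in the libraries labelled MDM2 shRNA and 9 higher and 3 lower (9 and 3 over the list alone, camera adjusted p = 0.19) with the PROTAC. The 17 epithelial genes had 4 higher and 3 lower (4 and 3 over the list alone, camera adjusted p = 0.949) in the libraries labelled MDM2 shRNA and 3 higher and 2 lower (3 and 2 over the list alone, camera adjusted p = 0.83) with the PROTAC. The 12 CDK inhibitors and D cyclins had 4 higher and 3 lower (4 and 4 over the list alone, camera adjusted p = 0.994) in the libraries labelled MDM2 shRNA and 3 higher and 3 lower (3 and 4 over the list alone, camera adjusted p = 0.949) with the PROTAC. 

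Markers of other cell types passed as a list in neither comparison of MDA-MB-436. The 5 leukocyte markers had 1 higher and 1 lower (1 and 1 over the list alone, camera adjusted p = 0.153) in the libraries labelled MDM2 shRNA and 3 higher and 1 lower (3 and 1 over the list alone, camera adjusted p = 0.0523) with the PROTAC. The 6 endothelial markers had 1 higher and 1 lower (1 and 1 over the list alone, camera adjusted p = 0.736) in the libraries labelled MDM2 shRNA and 1 higher and 1 lower (1 and 1 over the list alone, camera adjusted p = 0.981) with the PROTAC. The 6 fibroblast markers had 3 higher and 1 lower (3 and 1 over the list alone, camera adjusted p = 0.355) in the libraries labelled MDM2 shRNA and 3 higher and 1 lower (3 and 1 over the list alone, camera adjusted p = 0.477) with the PROTAC. The 8 luminal breast markers had 2 higher and 2 lower (2 and 2 over the list alone, camera adjusted p = 0.736) in the libraries labelled MDM2 shRNA and 2 higher and 2 lower (2 and 2 over the list alone, camera adjusted p = 0.736) with the PROTAC. The 6 liver, kidney and neural markers had 2 higher and 0 lower (2 and 0 over the list alone, camera adjusted p = 0.337) in the libraries labelled MDM2 shRNA and 2 higher and 0 lower (2 and 0 over the list alone, camera adjusted p = 0.19) with the PROTAC. In the libraries labelled MDM2 shRNA the median, the mean and the test did not share one sign for the CDK inhibitor, histone and luminal lists. With the PROTAC this held for the survival, serine, epithelial, CDK inhibitor, histone, endothelial and luminal lists.

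Of 30 lists, 13 (5 higher and 8 lower; 10 with an estimated correlation) passed in the libraries labelled MDM2 shRNA of MDA-MB-231 and 14 (5 higher and 9 lower; 8 with an estimated correlation) with the PROTAC. In MDA-MB-436 the numbers were 18 (7 higher and 11 lower; 12 with an estimated correlation) in the libraries labelled MDM2 shRNA and 17 (6 higher and 11 lower; 13 with an estimated correlation) with the PROTAC.

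**Figure D3:**
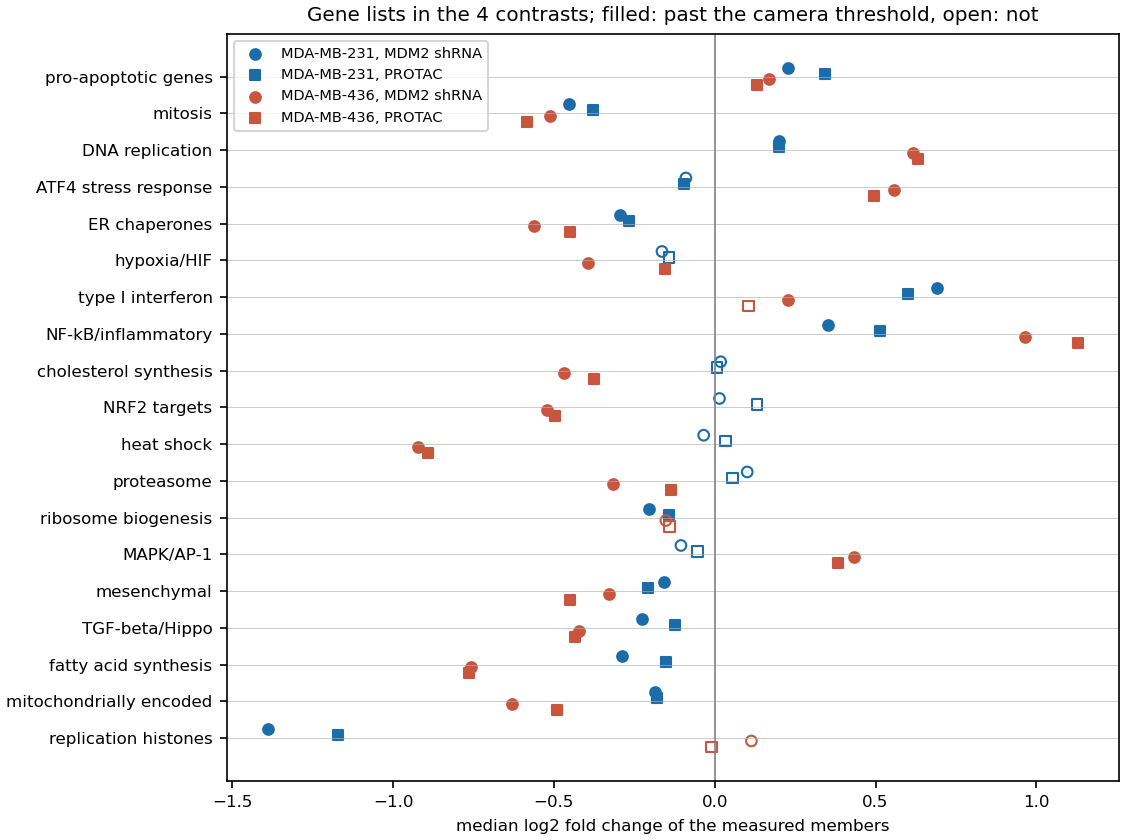
Median log2 change of 19 gene lists in the 4 comparisons, where a filled point marks a list past the camera threshold of 0.05. Heat-shock genes stand at -0.92 and -0.89 in MDA-MB-436 and near 0 in MDA-MB-231, and mitotic genes lie between -0.58 and -0.38 in all 4 comparisons.

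The libraries labelled MDM2 shRNA and the PROTAC libraries changed largely the same genes within a line. In MDA-MB-231, 1625 genes rose and 1799 fell in both comparisons, where 253.9 and 276.3 would be shared by independent calls, and 2 moved in opposite directions. In MDA-MB-436, 2929 rose and 2548 fell in both (independent calls would share 625.9 and 493.8), and 5 were opposite. The log2 changes correlated with r = 0.815 over 10842 genes with a mean over 8 CPM in MDA-MB-436 and with r = 0.733 over 10478 genes in MDA-MB-231, and with r = 0.616 and 0.464 over all genes tested. Since no fall of MDM2 RNA was called in the libraries labelled MDM2 shRNA, the overlap does not show that both treatments acted through MDM2.

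A direct test of the PROTAC effect minus the effect in the libraries labelled MDM2 shRNA passed for 1 gene in each line. In MDA-MB-231 it was MAFF (ENSG00000185022), a small MAF transcription factor, with a difference of -1.46 ± 0.14 (edgeR adjusted p = 0.0117). MAFF rose from 21.0 ± 1.82 to 94.4 ± 1.39 CPM in the libraries labelled MDM2 shRNA and from 19.7 ± 2.66 to 32.3 ± 2.49 CPM with the PROTAC. Without PROTAC replicate 2 of MDA-MB-231, the MAFF test fell short (edgeR adjusted p = 0.0687). In MDA-MB-436 the gene was RAB43 (ENSG00000172780), a small GTPase, with a difference of -1.86 ± 0.16 (edgeR adjusted p = 0.00378). RAB43 went from 8.48 ± 1.10 to 18.9 ± 1.19 CPM in the libraries labelled MDM2 shRNA and from 28.5 ± 1.98 to 17.5 ± 1.25 CPM with the PROTAC, so its controls differed. The RAB43 test fell short with a replicate block, and RAB43 drops out when genes with overlapping exons are left out. At an unadjusted p under 0.05, 977 genes stood in MDA-MB-231 and 1230 in MDA-MB-436, where chance gives 1034 and 1133. DESeq2 called 38 and 35 genes.

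**Figure D4:**
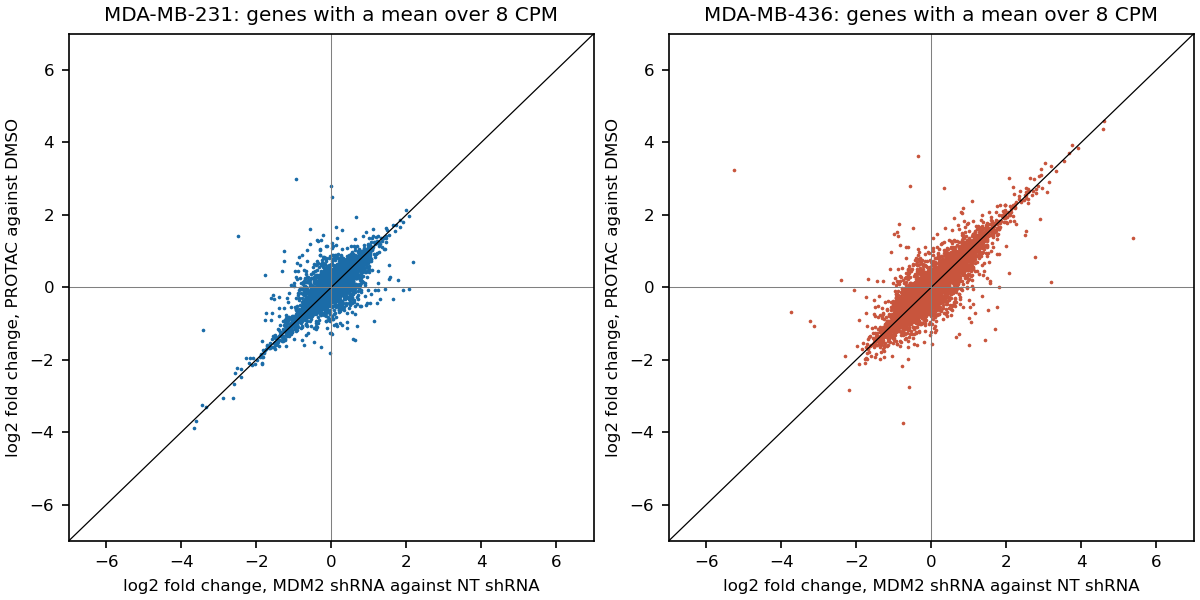
Log2 change with the PROTAC against log2 change in the libraries labelled MDM2 shRNA, one point per gene with a mean over 8 CPM, for each cell line. The points follow a common direction with r = 0.733 in MDA-MB-231 and r = 0.815 in MDA-MB-436.

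The lines were compared next. Among 19009 genes tested in both, 770 rose and 892 fell in the libraries labelled MDM2 shRNA of both lines, where independent calls would share 366.1 and 385.5, and 527 moved in opposite directions. With the PROTAC, 730 rose and 872 fell in both lines (389.7 and 399.1 by independent calls), and 660 were opposite. The log2 changes of the lines correlated with r = 0.265 and 0.309 over 9651 genes with a mean over 8 CPM, and with r = 0.0987 and 0.0825 over all genes tested in both. A test of the effect in MDA-MB-436 minus that in MDA-MB-231 passed for 4873 of 24719 genes (2457 positive and 2416 negative) in the libraries labelled MDM2 shRNA, and for 5508 (2910 and 2598) with the PROTAC.

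Genes called in the same direction in all 4 comparisons numbered 519 higher and 637 lower of 19009, where lines independent of each other would give 213.6 and 227.3. The 10 whose smallest change of the 4 was largest were TNFAIP3, an inhibitor of NF-kB, HSPB8, the docking protein gene NEDD9, GCNT4, C11orf96, the cytokine subunit gene EBI3 and the glutamate receptor gene GRM2, which rose, and MMP16, PLXDC2 and ARL15, which fell. NEDD9 rose by 1.84 ± 0.10 and 1.86 ± 0.10 in MDA-MB-231, and by 1.88 ± 0.25 and 1.66 ± 0.25 in MDA-MB-436, given first for the libraries labelled MDM2 shRNA. In the same order, HSPB8 rose by 2.35 ± 0.29, 1.78 ± 0.28, 2.18 ± 0.11 and 1.96 ± 0.11, and GRM2 by 2.4 ± 0.39, 3.83 ± 0.41, 1.86 ± 0.20 and 1.87 ± 0.20. MMP16, a membrane metalloproteinase, changed by -1.80 ± 0.24, -1.70 ± 0.24, -1.72 ± 0.13 and -1.98 ± 0.13, and PLXDC2 by -1.86 ± 0.15, -1.90 ± 0.15, -1.69 ± 0.22 and -1.77 ± 0.22. C11orf96 shares exons with an unnamed gene (ENSG00000254409).

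Whole lists also differed between the lines in a test added after the data were seen, adjusted over 60 tests. Past the threshold were 13 lists for the libraries labelled MDM2 shRNA and 15 for the PROTAC, or 7 and 6 with an estimated correlation. Heat-shock genes fell in MDA-MB-436 relative to MDA-MB-231, with median differences of -0.96 (camera adjusted p = 1.43e-31) and -0.95 (9.79e-29), given first for the libraries labelled MDM2 shRNA. In that order, differences were -0.48 (camera adjusted p = 2.59e-07) and -0.55 (2.59e-07) for sterol synthesis, -0.51 (8.27e-06) and -0.57 (7.03e-06) for NRF2 targets and -0.43 (7.88e-08) and -0.66 (1.25e-09) for fatty acid synthesis. Replication genes rose more in MDA-MB-436, by 0.57 (camera adjusted p = 2.22e-12) and 0.52 (1.03e-10). With an estimated correlation these 5 lists had adjusted p from 0.000165 to 0.0407.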

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

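The tests of differences between effects on genes and the counts over other splits of the libraries were set before the data were examined, and the other tests here were chosen after the results were seen.

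Effects that differed between groups were picked out by a test of the difference itself. The PROTAC effect minus the effect in the libraries labelled MDM2 shRNA passed for 1 gene in MDA-MB-231 (MAFF, -1.46 log2) and 1 gene in MDA-MB-436 (RAB43, -1.86). The effect in MDA-MB-436 minus that in MDA-MB-231 passed for 4873 genes in the libraries labelled MDM2 shRNA and 5508 with the PROTAC. By the naming rule, the differences in the libraries labelled MDM2 shRNA were 8.25 for ST6GALNAC3, 8.06 for NEURL3, 7.82 for PCSK1, 7.60 for COL4A6, -7.08 for SLC8A1, -6.60 for TBX18, -6.37 for MATK and -6.37 for NPPB. With the PROTAC they were 8.88 for C6orf58, 8.55 for CD96, 8.09 for CXCL11, 8.01 for DMC1, -10.66 for AC009336.2, -7.11 for ALPK2, -7.01 for PTPN20 and -6.50 for MGAT3. These fitted differences rest on counts near 0 in a line or group and are not bounds.

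Lists whose effect differed between the lines were picked out in the same way. Median differences in the libraries labelled MDM2 shRNA were 0.57 for replication genes, -0.48 for sterol synthesis, -0.51 for NRF2 targets, -0.96 for heat-shock genes and -0.43 for fatty acid synthesis. With the PROTAC they were 0.52, -0.55, -0.57, -0.95 and -0.66 in the same order. The labels give the cell line as the difference, and no explanation for it was tested.

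In each comparison the real grouping of the 6 libraries gave more genes than the other splits into 3 and 3, but 10 splits are too few for a share under 0.05, since 1 of 10 is the smallest share. The real values in MDA-MB-231 were 4694 in the libraries labelled MDM2 shRNA and 4668 with the PROTAC, and the highest other splits gave 5 and 3 genes. In MDA-MB-436 the real values were 6896 and 7334, and the highest other splits gave 2 and 1.

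Libraries of the hairpin and PROTAC experiments resembled each other in MDA-MB-231, where no fall of MDM2 RNA was called. With the MDM2 shRNA label, its fold had lower 95% bounds of 1.01 in MDA-MB-231 and 0.661 in MDA-MB-436. Shared exons leave a 2-fold fall open. In MDA-MB-231 the mean distance between libraries of different experiments was at most 1.01 times the mean within a group, although single pairs of controls reached 0.346 against 0.337 within groups. There edgeR called 0 genes between DMSO and the non-targeting shRNA (903 at an unadjusted p under 0.05, where chance gives 1034; voom 0, DESeq2 40). One set of cultures under both labels is a candidate explanation there. Against it, edgeR called 3 genes (MAFF, LYRM7 and MAP2K6) between the PROTAC libraries and those labelled MDM2 shRNA (1113 unadjusted, voom 2, DESeq2 48), with MAFF at 32.3 ± 2.49 and 94.4 ± 1.39 CPM. In MDA-MB-436 the ratio was 1.11, and 4 genes (RAB43, DNAL1, ETS1 and LST1) were called between the controls, with 2579 at an unadjusted p under 0.05 where chance gives 1133, 3 by voom and 148 by DESeq2. Genes are correlated, so 1133 is no bound. Between the treated groups edgeR called 1 gene, DNAL1 (1051 unadjusted, voom 1, DESeq2 39), and the explanation stays open in that line. Alike effects of both treatments, or a difference of handling between treated and control libraries, stay open in both lines.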

How the results depend on the processing

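Counts divided by 4, and leaving out genes with overlapping exons, were chosen after seeing the data. Depth sets a floor of 3 counts, which is 0.017 to 0.090 CPM in single libraries. In simulations, where few genes were changed, 1.5-fold changes were mostly missed. Among named genes, 7434 of 7612 alternative values kept their direction and side of the threshold, 173 lost the call and 5 reversed, and with a library left out 3343 of 3504 were kept, 153 lost the call, 1 gained it and 7 reversed. Unless the setting itself shows it (a stricter threshold, fewer genes tested), the cause was not tested. Without scaling, genes higher in the libraries labelled MDM2 shRNA of MDA-MB-231 numbered 3564, genes lower in MDA-MB-436 numbered 1937 and 2203 (PROTAC), and in the libraries labelled MDM2 shRNA of MDA-MB-436 MDM2 reversed to 0.0717 and TP63 to 0.103. At an adjusted p of 0.01, counts in MDA-MB-231 were 1246 higher and 1524 lower (libraries labelled MDM2 shRNA) and 1342 and 1490 (PROTAC), 2158 were lower in the libraries labelled MDM2 shRNA of MDA-MB-436, 3105 and 3538 differed between lines, 2101 were shared by both treatments in MDA-MB-231, 901 and 882 by both lines and 654 by all 4 comparisons. At that threshold edgeR called 0 differences between treatments in MDA-MB-231 (977 at an unadjusted p under 0.05, DESeq2 38 and 35 genes at 0.05 in the lines). Without genes whose exons overlap another gene, where MDM2 could not be tested, counts higher and lower were 1329 and 1337, then 1327 and 1327 in MDA-MB-231 and 1953 and 1750, then 2058 and 1886 in MDA-MB-436, lists past the threshold with the PROTAC in MDA-MB-231 were 9, line differences 2518 and 2890, shared genes 1982 and 2964 by treatment, 954 and 905 by line and 670 in all 4 comparisons, and edgeR called 0 treatment differences in MDA-MB-436 (1230 unadjusted among all genes). MDM2 with the PROTAC in MDA-MB-436 passed with the filter of 1 CPM (-0.60), DESeq2 (-0.62), counts divided by 4 (-0.61) and the 6 libraries alone (-0.60, where treatment differences could not be run), with adjusted p from 0.0188 to 0.184 over all its settings. Lists past the threshold were 23 (libraries labelled MDM2 shRNA) and 25 (PROTAC) in MDA-MB-231 by fry, which tests a list against no change instead of against the other genes, and 8 (PROTAC) with an estimated correlation. With voom, MDM4 in MDA-MB-231 reversed to 0.27 and TP63 in MDA-MB-436 to 0.21. Without scaling, camera adjusted p rose past the threshold in MDA-MB-231 for ATF4 stress (0.102) and ribosome biogenesis (0.15) with the PROTAC and for mitochondrial transcripts (0.0934) in the libraries labelled MDM2 shRNA, and in MDA-MB-436 for the proteasome (0.324) with the PROTAC. Lists gained without scaling were the proteasome in both comparisons of MDA-MB-231 (0.00244 and 0.0205) and, with the PROTAC in MDA-MB-436, interferon (0.0405) and autophagy (0.0405). Without genes whose exons overlap another gene, the mitochondrial list (0.187 and 0.118) and ATF4 stress with the PROTAC (0.742) were lost in MDA-MB-231, as was the proteasome with the PROTAC in MDA-MB-436 (0.369). Gained there were ribosome biogenesis, lower in MDA-MB-436 (0.0367 and 0.0346), and in MDA-MB-231 serine and one-carbon genes, lower (0.0252), and the proteasome, higher (0.0483), in the libraries labelled MDM2 shRNA and luminal markers, lower (0.0497), with the PROTAC. Interferon in the libraries labelled MDM2 shRNA of MDA-MB-436 was lost with the filter of 1 CPM (0.0926), counts divided by 4 (0.0779) and the 6 libraries alone (0.0511), and the proteasome with the PROTAC in that line by the same settings (0.0994, 0.0699 and 0.0671). With the PROTAC in MDA-MB-231, the filter of 1 CPM ended the mesenchymal call (0.0557). With the 6 libraries alone, mesenchymal genes in the libraries labelled MDM2 shRNA (0.106) and ATF4 stress with the PROTAC (0.0684) were lost in MDA-MB-231, and leukocyte markers passed as higher with the PROTAC in MDA-MB-436 (0.0368).

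Replicate numbers did not pair libraries (correlations of -0.03 to 0.04 for the same number), so a replicate block tests nothing about pairing. With the block, MDM2 with the PROTAC in MDA-MB-436 was -0.61 (past the threshold), MDM4 in MDA-MB-231 reversed to 0.14 and TP63 in MDA-MB-436 to 0.42, and edgeR called 0 treatment differences in MDA-MB-436, where DESeq2 without it called 35. The block also ended the list calls of mesenchymal genes (0.0503 and 0.0618) and of ATF4 stress with the PROTAC (0.075) in MDA-MB-231.

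Leaving out one library each, MDM2 in the libraries labelled MDM2 shRNA of MDA-MB-436 ranged from -0.27 to 0.13 (without MDM2 shRNA replicate 1), and in MDA-MB-231 MDM2 ranged from 0.29 (without non-targeting replicate 3) to 0.74 in the libraries labelled MDM2 shRNA and from 0.12 to 0.48 with the PROTAC. Treatment differences ranged from 0 (without PROTAC replicate 2) to 6 (without PROTAC replicate 1) in MDA-MB-231 and from 1 to 25 (without PROTAC replicate 2) in MDA-MB-436. In the libraries labelled MDM2 shRNA, MDM4 ranged from -1.53 to 1.74 (without non-targeting replicate 2) in MDA-MB-231 and from -0.52 (without MDM2 shRNA replicate 3) to 2.12 in MDA-MB-436, and TP63 in MDA-MB-436 from -0.70 to 0.37 (without non-targeting replicate 3).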

Other observations

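The tests of partial correlation with span and of genomic DNA were set before their results were seen, and the others here after.

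Genes with a long genomic span fell in MDA-MB-231 with both treatments. Against genes under 100 kb matched on transcript length, GC content and expression, genes over 400 kb were lower by median gaps of -1.12 (libraries labelled MDM2 shRNA) and -1.06 (PROTAC), which argues against RNA quality that follows transcript length. The gaps were -1.14 and -1.09 among genes without overlapping exons, which argues against shared reads. Log2 change also fell with span between 20 and 400 kb, with partial rank correlations of -0.257 and -0.241. In MDA-MB-436 the same gaps were smaller, -0.228 and -0.252 (-0.138 and -0.243, with intervals that include 0, without overlapping exons), and the correlations were -0.0885 and -0.117. A candidate explanation, as a hypothesis, is less RNA made from long genes, with a difference of handling between treated and control libraries left open.

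More genes were detected at one total in treated MDA-MB-436 libraries, by 1242 on average, and 5 of the 6 treated libraries (22742 to 22959) lay well above the highest control (21487), so depth is excluded for them. PROTAC replicate 3, the only library not thinned, stood apart at 21554, close to the controls. RNA of MDA-MB-231 cells is argued against, since 55 genes of that line reached a median of 0.095% of their level there. Olfactory receptor genes rose 2.33 times in summed CPM (1.52 to 3.55), so reads from genomic DNA may add to the detected genes. Genes at least 2-fold higher in both comparisons were chosen for gaining, so they do not test this. Of 1088, 99.9% gained over 10 times the olfactory gain in CPM per kb. Broader transcription in treated cells was not tested.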
